A study of Mus musculus with 12 samples.

How the data were processed

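Gene expression was measured on 12 one-colour arrays in cultures of mouse blood stem and progenitor cells, which the labels describe as enriched for cells without lineage markers. A protocol field in the labels also speaks of leukaemia progenitor lines, and what that covers was not given in the sources used here. The cells had been infected with retroviruses and grown in medium with stem cell factor, the ligand of the Kit receptor. Each of the 3 arms received NRAS G12D, an activated form of the small GTPase NRAS. The EV arm received nothing further that the labels name, the RH arm also received DNMT3A R882H, and the WT arm also received wild-type DNMT3A, a DNA methyltransferase. RNA was taken on day 12 and day 16 after infection, with 2 arrays per arm and day, which makes 6 groups. Groups were taken from the sample titles.

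The authors deposited a table of log2 values for 41345 probe sets on the 12 arrays. Per the labels' protocols, total RNA was purified on columns, and fragmented cDNA was end-labelled with biotin for Affymetrix whole-transcript arrays. The normalization and summary method behind the deposited log2 values was not given in the sources used here. That the scale is log2 was judged from the range of the values, which ran from 1.05 to 13.98, and not from a statement. Direction was not in question, since each array held 1 sample. Array medians over all probe sets ranged from 4.55 to 4.67, so the arrays had been brought to a similar level but not to identical distributions, and the largest difference between the sorted values of the first array and any other was 0.21. How background was treated stays unknown, scanner files and detection p-values were not used here, and a low log2 value therefore cannot be told apart from absence of the transcript. The number of arrays limits the precision.

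Probe sets were named through the platform's annotation table. It paired 23521 probe sets with exactly 1 gene symbol and 1814 with several, and 16010 were not named there. Of the 23521 single-symbol probe sets, 23328 were found by Entrez identifier in the RefSeq table of assembly GRCm38.p6, and 0 symbols had to be updated. Probe sets with several symbols or none were left out of the gene test. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over the 12 arrays stood for the gene, which left 22180 genes. No genome coordinates are given because the build behind the array annotation was not given in the sources used here. Probe sets of close paralogs, such as the stefin A, Tps, Mcpt, Hspa1 and Ly6 genes, could cross-hybridise, so their values are uncertain as to which copy they measure.

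Log2 values were used as deposited, with no filter on dim probe sets. In R 4.3.3, limma 3.58.1 was used to fit the 6 group means with lmFit and moderated variances with eBayes, so that all groups shared an estimate of the spread, with 6 residual and 2.19 prior degrees of freedom. The contrasts were RH minus WT, RH minus EV and WT minus EV on day 12, on day 16 and as the mean of both days, day 16 minus day 12 within each arm, and the 3 interactions of arm difference with day, 15 in all. Tests were two-sided, Benjamini-Hochberg adjustment ran over the 22180 genes within a contrast, and a gene passed at an adjusted p under 0.05. Differences are on the log2 scale with their standard error, and group means are followed by the SD of the 2 arrays. The median within-group SD over genes was 0.124.

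A set of 27 gene lists with 464 genes, of which 415 were measured, was written down before the data were examined, as were the contrasts, the tests, the alternatives and the rule for naming genes. The lists were the Hoxa cluster, the Hoxb cluster, stem cell and leukaemia transcription factors, stem and progenitor surface and niche genes, primary granule and myeloblast genes, late neutrophil genes, monocyte and macrophage genes, dendritic cell and MHC class II genes, mast cell and basophil genes, eosinophil genes, erythroid genes, megakaryocyte genes, B lymphoid genes, T and NK cell genes, stromal and endothelial genes, cell cycle genes, RAS-MAPK output genes, p53 and senescence genes, interferon response genes, inflammatory cytokine and chemokine genes, DNA methylation machinery genes, germline genes silenced by DNA methylation, imprinted genes, ribosome biogenesis and MYC target genes, stress response and integrated stress response genes, hypoxia and glycolysis genes, and cholesterol synthesis genes. Each list was tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 27 lists within a contrast. Camera asks whether a list moved relative to the other genes. It was run again with the correlation estimated from the residuals, and fry was run beside it. The p of fry tests whether the genes of a list moved on balance in a single direction, with no comparison to other genes. List members not measured by a single-symbol probe set were not analysed here.

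The genes named were chosen by rule. In each mean-of-both-days and each day contrast they were the 8 with the largest increase and the 8 with the largest decrease among genes that passed and whose arrays did not overlap, leaving out predicted gene models, small RNAs and olfactory and vomeronasal receptors. In every contrast up to 4 members of each list with the smallest p among those that passed were added, and 14 genes, including Dnmt3a, Nras, Hoxa9, Meis1, Mn1, Kit, Cd34, Itgam and Csf1r, were always reported.

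The gene test was tested on simulated data with the spread of the real genes, in which a few of the 22180 genes were changed. For RH minus WT as the mean of both days it recovered 67.2% of 67 genes changed 1.5-fold, 91% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, and 12 unchanged genes were called. For the same arms on day 12 it recovered 56.7%, 80.6% and 97% at these folds, and 10 unchanged genes were called. In the real mean-of-both-days contrast 31.46% of genes passed. With so few genes changed the adjusted threshold was stricter than there, and the simulated noise was independent between genes. These rates thus describe the simulated setting and not the real test.

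Alternatives tried were quantile normalization between arrays, centring of each array on its median, filters at the 25th percentile and at the median of mean level, every probe set as a row, the mean of a gene's probe sets, eBayes with trend and robust settings, a fit with only the arrays compared, the replicate number as a block, arm and number as a random block, array weights, and leaving out each array in turn. The labels do not say that arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. No slide, scan or hybridisation batch was given in the sources used here. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the plots.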

Results

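Expression was measured on 12 arrays of cultured mouse blood progenitors that carried NRAS G12D alone (EV arm), with DNMT3A R882H (RH arm) or with wild-type DNMT3A (WT arm). There were 4 arrays per arm, 2 from day 12 and 2 from day 16 after infection. R882H is a recurrent substitution of DNMT3A in acute myeloid leukaemia, where it can occur together with NRAS mutations. Replicate arrays correlated at 0.9965 to 0.9974 over the 22180 genes, and the median absolute difference between them was 0.101 to 0.112 on the log2 scale. The first principal component held 37.0% of the variance and placed the WT arrays, at -38.5 to -37.6, apart from the RH arrays, at 16.7 to 36.1. On it the EV arrays moved from -11.3 and -10.6 on day 12 to 34.5 and 34.3 on day 16. The second held 27.6% and was lower on day 16 than on day 12 in all 3 arms, by most in EV and WT.

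Dnmt3a (probe set 17273652) had a log2 level of 8.45 ± 0.01 in EV, 8.96 ± 0.08 in RH and 8.71 ± 0.07 in WT on day 12 (SD, n = 2), and of 8.99 ± 0.03, 9.01 ± 0.04 and 8.60 ± 0.01 on day 16. As the mean of both days it was 0.33 ± 0.04 higher in RH than in WT (SE, adjusted p = 0.000551), and WT was higher than EV by 0.26 ± 0.06 on day 12 (adjusted p = 0.036) and lower, at -0.38 ± 0.06, on day 16 (adjusted p = 0.00207). RH was higher than EV by 0.51 ± 0.06 on day 12 (adjusted p = 0.00112) and differed from it by 0.02 ± 0.06 on day 16 (adjusted p = 0.89). Between the days it rose in EV by 0.54 ± 0.06 (adjusted p = 0.000253), and the changes of 0.05 ± 0.06 in RH and -0.10 ± 0.06 in WT did not pass (adjusted p = 0.717 and 0.306). Nras (probe set 17401117) lay between 10.09 and 10.28 on all 12 arrays. The labels do not say from which species the constructs came or whether they hold the sequence the probes read, so these probe sets do not check the labels.

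The first comparison asked how cells with R882H differed from cells with wild-type DNMT3A, both with NRAS G12D. Hoxa9 (probe set 17466863), a homeobox factor of progenitor self-renewal, was 5.19-fold higher in RH as the mean of both days, with levels of 9.46 ± 0.02 against 7.30 ± 0.13 on day 12 and 10.07 ± 0.01 against 7.47 ± 0.37 on day 16 (SD, n = 2). Its partner Meis1 (probe set 17260815) was 3.32-fold higher and the co-regulator Mn1 (probe set 17440633) 4.03-fold higher, with all RH arrays above all WT arrays on each day. Genes of mast cells and megakaryocytes were higher in RH, while genes of neutrophils, monocytes and B cells and interferon response genes were lower.

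**Figure D1:**
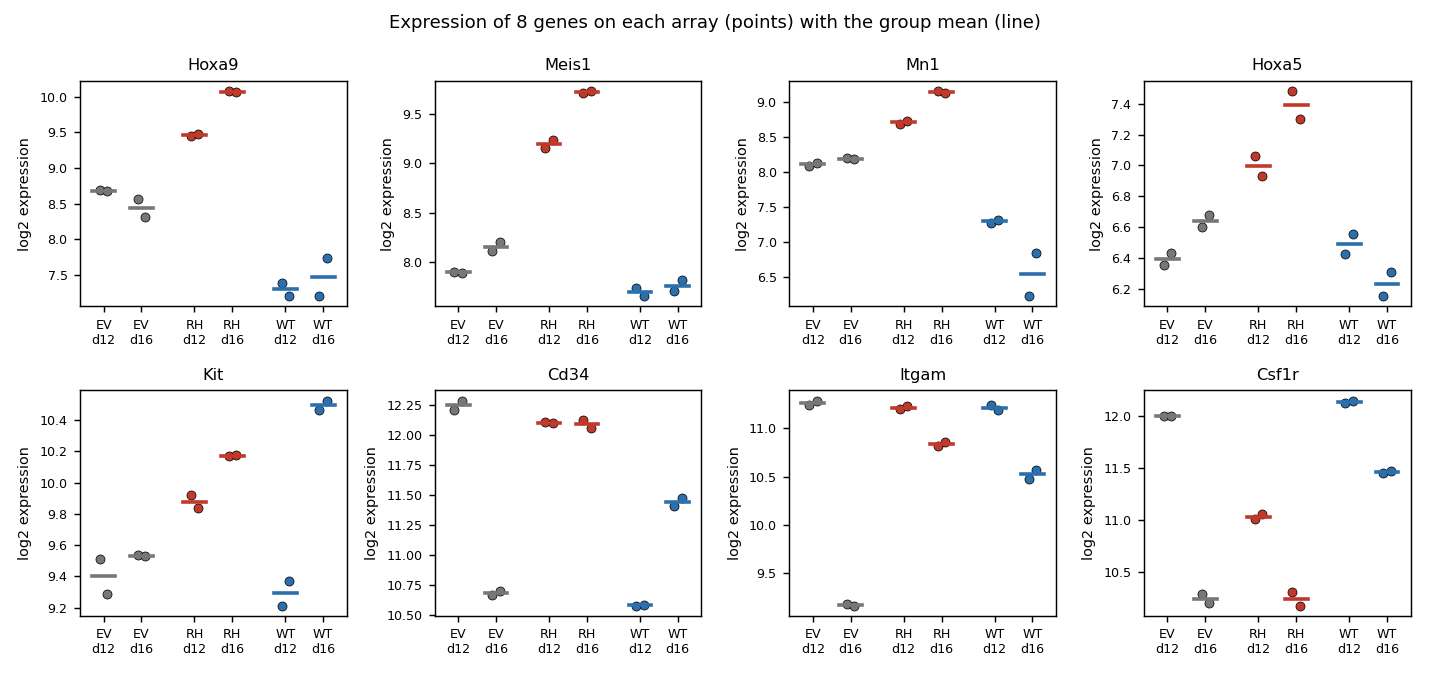
Log2 expression (vertical axes) of 8 genes on each of the 12 arrays, by arm and day (d12, d16; horizontal axes); points are arrays, lines are means of the 2 arrays, and the vertical axes do not start at 0. Hoxa9, Meis1 and Mn1 were highest in the RH arm on both days, and Itgam and Cd34 were lower in EV on day 16 than on day 12.

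In RH minus WT, 6 of 9 measured Hoxa cluster genes were higher and 0 lower, with the same counts adjusted over the list alone and a median difference of 0.83 (camera adjusted p = 3.43e-05). Hoxa9 differed by 2.38 ± 0.11, Hoxa6 by 1.16 ± 0.07, Hoxa10 by 1.05 ± 0.10 and Hoxa5 by 0.83 ± 0.07, whereas Hoxa7 differed by 0.05 ± 0.04 (adjusted p = 0.467). Of 10 Hoxb genes 2 were higher, Hoxb6 by 1.14 ± 0.15 and Hoxb5 by 0.70 ± 0.14, and 2 were lower, 3 adjusted over the list alone. Hoxb6 and Hoxb5 did not pass on day 12, at 0.20 ± 0.21 and 0.10 ± 0.20 (adjusted p = 0.581 and 0.796). On day 16 they were higher by 2.08 ± 0.21 and 1.30 ± 0.20 (adjusted p = 0.000127 and 0.0014). Hoxb3 was lower on day 12, at -0.48 ± 0.11, and higher on day 16, at 0.51 ± 0.11 (adjusted p = 0.0166 and 0.0103). The stem cell and leukaemia transcription factors split, with 9 of 22 higher and 5 lower (10 and 6 adjusted over the list alone) and no call for the list (camera adjusted p = 0.104). Gata2, needed in stem and mast cells, was higher by 2.26 ± 0.06 and Gfi1b, of the megakaryocyte and erythroid lines, by 1.65 ± 0.05, while the ETS factor Erg was lower, at -2.35 ± 0.09, and Pbx3 was lower, at -0.78 ± 0.12. The stem and progenitor surface list was not called (camera adjusted p = 0.466), with 6 of 18 higher and 5 lower (7 and 5 adjusted over the list alone). In it Flt3 was higher by 1.16 ± 0.05 and Cd34 by 1.09 ± 0.04, and Kit was higher by 0.58 ± 0.09 on day 12 (adjusted p = 0.00148) but lower, at -0.32 ± 0.09, on day 16 (adjusted p = 0.0247).

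Of 20 late neutrophil genes 16 were lower in RH than in WT and 2 higher, with a median of -1.78 (camera adjusted p = 1.11e-10). Chil3 differed by -4.30 ± 0.20, the antimicrobial peptide gene Camp by -3.90 ± 0.19, and Ltf, which encodes lactoferrin, by -3.09 ± 0.06, and Il1r2, a decoy receptor for interleukin 1, went the other way, at 2.69 ± 0.07. Of 12 primary granule genes 9 were lower and 1 higher (median -0.75, camera adjusted p = 8.03e-06), among them the proteases Ctsg, at -2.55 ± 0.04, and Elane, at -2.21 ± 0.05. Of 21 monocyte genes 18 were lower and 0 higher (median -0.84, camera adjusted p = 3.77e-13), with Mrc1 at -2.05 ± 0.05 and Csf1r at -1.16 ± 0.05. All 12 B lymphoid genes were lower (median -1.86, camera adjusted p = 3.77e-13). The surrogate light chain gene Igll1 differed by -3.03 ± 0.05, and the B lineage factors Ebf1 by -2.04 ± 0.05 and Pax5 by -1.87 ± 0.05. Of 19 interferon response genes 16 were lower and 0 higher (camera adjusted p = 3.42e-10), Rsad2 by -1.20 ± 0.05 and Isg15 by -0.86 ± 0.05. Adjusted over the list alone, these 5 counts were the same.

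Higher in RH than in WT were 13 of 19 mast cell and basophil genes, with 1 lower (14 and 1 adjusted over the list alone; median 1.14, camera adjusted p = 1.12e-10). The tryptase genes Tpsb2 and Tpsab1 differed by 2.53 ± 0.06 and 2.27 ± 0.06, and Fcer1a, of the IgE receptor, by 2.46 ± 0.08. Of 12 megakaryocyte genes 10 were higher and 2 lower, also adjusted over the list alone (median 1.66, camera adjusted p = 2.1e-07), with the platelet chemokine gene Ppbp 41.0-fold higher. Of 14 dendritic cell and MHC class II genes 9 were higher and 1 lower (11 and 2 adjusted over the list alone; median 0.70, camera adjusted p = 6.76e-06), with H2-Ab1 at 2.28 ± 0.05. Of 17 ribosome biogenesis and MYC target genes 16 were higher, also adjusted over the list alone, by a small median of 0.29 (camera adjusted p = 7.08e-08). Of 20 RAS-MAPK output genes 12 were higher and 3 lower (13 and 4 adjusted over the list alone; camera adjusted p = 0.00603). The feedback inhibitors Spry2 and Spry1 differed by 1.79 ± 0.06 and 1.60 ± 0.06, and the immediate early gene Fos by -1.14 ± 0.04. The largest increases of single genes after Ppbp were in the granzyme gene Gzmc (5.30 ± 0.19), Mab21l2 (4.64 ± 0.07), Dkkl1 (4.54 ± 0.14), Tshz3 (4.33 ± 0.08) and Gzma (4.26 ± 0.11).

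Calls of 3 lists in RH minus WT ended with an estimated correlation. Of 15 p53 and senescence genes 7 were higher and 1 lower (8 and 2 adjusted over the list alone; adjusted p = 0.154 with an estimated correlation), and quantile normalization ended this call too. Of 23 inflammatory cytokine and chemokine genes 11 were higher and 4 lower, also adjusted over the list alone (adjusted p = 0.0632 with an estimated correlation). Of 10 DNA methylation machinery genes 5 were higher and 1 lower, also adjusted over the list alone (adjusted p = 0.125 with an estimated correlation). In the last, Tet1 was higher by 2.41 ± 0.13 and Dnmt3b by 1.14 ± 0.09. Dnmt3b did not pass on day 12, at 0.35 ± 0.13 (adjusted p = 0.0907), and was higher by 1.92 ± 0.13 on day 16 (adjusted p = 8.51e-06). The germline genes, which promoter methylation keeps silent in body cells, were not called (camera adjusted p = 0.21), and of 19 only Ddx4 passed, at -0.29 ± 0.09, with 0 adjusted over the list alone. Of 17 imprinted genes 5 were higher and 5 lower (6 and 5 adjusted over the list alone), with Dlk1 at 2.94 ± 0.11 and Igf2r at 1.49 ± 0.05, and the list was not called (camera adjusted p = 0.198). Of 8 eosinophil genes 3 were higher and 1 lower, of 12 erythroid genes 5 and 2, and of 14 T and NK cell genes 6 and 5 (camera adjusted p = 0.198, 0.0658 and 0.13). Of 15 stromal and endothelial genes 3 were higher and 4 lower, of 24 cell cycle genes 3 and 0, and of 15 stress response genes 3 and 4 (camera adjusted p = 0.665, 0.236 and 0.835). Of 12 hypoxia and glycolysis genes 4 were higher and 3 lower, and of 10 cholesterol synthesis genes 4 and 1 (camera adjusted p = 0.909 and 0.4). Adjusted over the list alone, 4 eosinophil genes were higher, 4 stress response genes were higher and 5 lower, 2 cholesterol genes were lower, and the other counts of these 8 lists were the same. Among markers of other cell types, Cd3g and Tbx21, of T and NK cells, differed by 2.64 ± 0.12 and 2.35 ± 0.08. The stromal genes Fn1 and Postn went opposite ways, at -2.99 ± 0.10 and 2.78 ± 0.16. For the Hoxb list the median was -0.13 and the mean 0.07, and for the stress response list they were 0.06 and -0.14.

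Some of these differences in RH minus WT were called on a single day. The primary granule list was not called on day 12, with 3 genes higher and 2 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.397). On day 16, 8 were lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 1.07e-07), with Ctsg at -4.92 ± 0.06 and Elane at -4.40 ± 0.08. Of the interferon response genes 4 were higher and 7 lower on day 12 (4 and 8 adjusted over the list alone; camera adjusted p = 0.354), and 18 were lower on day 16 (19 adjusted over the list alone; camera adjusted p = 1.25e-15). Of the dendritic cell and MHC class II genes 5 were higher and 3 lower on day 12, also adjusted over the list alone (camera adjusted p = 0.328), and 12 were higher on day 16 (12 and 1 lower adjusted over the list alone; camera adjusted p = 4.55e-10). The RAS-MAPK output list was called on day 12, with 14 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 5.83e-06). On day 16, 6 of its genes were higher and 6 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.829). The interaction of arm and day was called for these 4 lists, with medians of -1.84, -0.92, 1.31 and -0.53 (camera adjusted p = 5.38e-09, 8.43e-19, 7.96e-12 and 7.47e-07), also with an estimated correlation.

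As the mean of both days 6977 of 22180 genes differed between RH and WT in limma, 3483 higher and 3494 lower in RH, and 1104 of them by at least 2-fold. On day 12 the count was 4999 (2390 higher, 2609 lower) and on day 16 it was 5814 (3084 higher, 2730 lower). Both arrays of an arm lay on the same side of both arrays of the other for 13034 of the 22180 genes on day 12 and for 13352 on day 16, which by chance happens for 33.3% of genes with 2 arrays against 2. With each array centred on its median, which moved the median gene by -0.106 on day 12, the split on that day became 1646 higher and 4292 lower, and that of the mean of both days 2640 and 5066. The median gene was at -0.036 on day 12 before centring, so centring took it further from 0. Centring used the median over all probe sets, including those outside the gene test. Quantile normalization moved the median gene by -0.006 on that day.

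**Figure D2:**
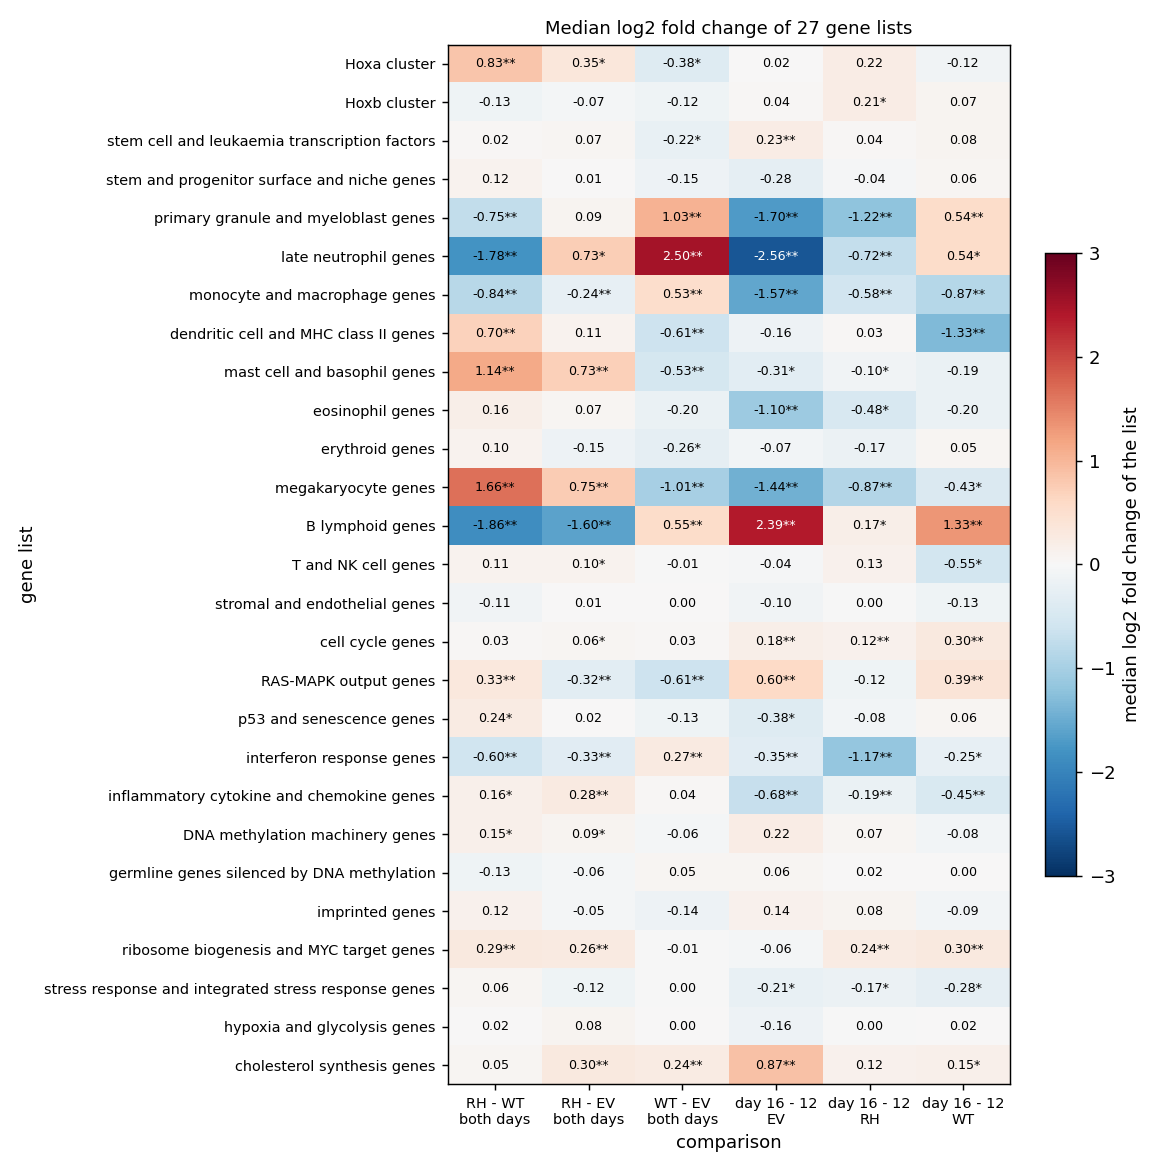
Median log2 fold change (colour, red higher and blue lower, limited at 3 on either side) of 27 gene lists (vertical axis) in 6 comparisons (horizontal axis), with the value in each cell; 1 star marks a camera adjusted p under 0.05 at the preset correlation and 2 stars mark calls that also hold with an estimated correlation. The late neutrophil list reached 2.50 in WT minus EV, and the B lymphoid list -1.86 in RH minus WT.

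The second comparison set R882H with NRAS G12D against NRAS G12D alone. Hoxa9 was higher in RH by 1.20 ± 0.11, Meis1 by 1.43 ± 0.05 and Mn1 by 0.78 ± 0.12 as the mean of both days, and Gata2 by 1.27 ± 0.06. Lower in RH were the endothelial and stem cell co-receptor gene Eng, at -2.26 ± 0.05, the zinc finger oncogene Mecom, at -1.77 ± 0.04, and Erg, at -2.01 ± 0.09. B lymphoid genes were lower than in EV and mast cell and megakaryocyte genes higher, while monocyte genes were lower and cholesterol synthesis genes higher on day 12.

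In RH minus EV, 4 of 9 Hoxa genes were higher and 0 lower (7 and 0 adjusted over the list alone; median 0.35, adjusted p = 0.0716 with an estimated correlation). Of 12 B lymphoid genes 11 were lower, also adjusted over the list alone (median -1.60, camera adjusted p = 1.17e-14). Cd22 differed by -2.10 ± 0.08, Pax5 by -1.65 ± 0.05 and Igll1 by -1.59 ± 0.05. The complement receptor gene Cr2 had the largest decrease among the genes named for this comparison, at -3.92 ± 0.09. Of 21 monocyte genes 14 were lower and 0 higher (16 and 0 adjusted over the list alone; median -0.235, camera adjusted p = 3.07e-09), with the lineage factor Irf8 at -1.09 ± 0.04 and the chemokine receptor Ccr2 at -1.06 ± 0.06. Of 19 mast cell genes 14 were higher and 2 lower (15 and 2 adjusted over the list alone; median 0.73, camera adjusted p = 1.21e-09), with Fcer1a at 1.64 ± 0.08 and Hdc, the histamine-forming enzyme, at 1.21 ± 0.05 but the protease gene Mcpt2 at -3.23 ± 0.12. Of 12 megakaryocyte genes 9 were higher and 0 lower (11 and 1 adjusted over the list alone; median 0.75, camera adjusted p = 3.37e-08), with the integrin genes Itgb3 at 1.24 ± 0.07 and Itga2b at 1.06 ± 0.08.

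Of 20 RAS-MAPK output genes 13 were lower in RH than in EV and 2 higher (14 and 2 adjusted over the list alone; median -0.32, camera adjusted p = 4.39e-05), with Egr1 at -1.31 ± 0.08, Phlda1 at -1.09 ± 0.07 and Fos at -0.77 ± 0.04. Of 10 cholesterol synthesis genes 8 were higher (9 adjusted over the list alone; median 0.30, camera adjusted p = 2.3e-07), with Lss at 0.63 ± 0.05 and Hmgcs1 at 0.51 ± 0.05. Of 17 ribosome biogenesis genes 14 were higher (15 adjusted over the list alone; median 0.26, camera adjusted p = 6.68e-10), with Cad at 0.50 ± 0.04. Of 23 inflammatory genes 12 were higher and 3 lower (13 and 3 adjusted over the list alone; camera adjusted p = 0.000305), with the chemokine genes Ccl5 at 1.14 ± 0.04 and Ccl2 at 1.07 ± 0.05. Of 19 interferon response genes 13 were lower and 2 higher, also adjusted over the list alone (median -0.33, camera adjusted p = 0.000104), with Oasl1 at -0.69 ± 0.04 but Cxcl10 at 0.83 ± 0.07. Of 20 late neutrophil genes 13 were higher and 5 lower (13 and 6 adjusted over the list alone; median 0.73, adjusted p = 0.0716 with an estimated correlation), with Ly6g at 1.52 ± 0.06 and Mmp9 at -1.68 ± 0.04.

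In RH minus EV the calls of the T and NK cell list (5 of 14 higher, 2 lower), the cell cycle list (3 of 24 higher) and the DNA methylation machinery list (4 of 10 higher) also ended, at an adjusted p = 0.116, 0.0901 and 0.0901 with an estimated correlation. Adjusted over the list alone, these counts were 6 and 2, 2, and 4. Ncr1, a receptor gene of NK cells, was higher by 2.52 ± 0.21, Cd3g by 1.97 ± 0.12 and Dnmt3b by 0.87 ± 0.09. By day, Dnmt3b differed by 0.09 ± 0.13 on day 12 (adjusted p = 0.733) and by 1.64 ± 0.13 on day 16 (adjusted p = 3.27e-05). The largest increases were in Syce1 (4.05 ± 0.13), Jchain (3.30 ± 0.09), Sdc2 (3.12 ± 0.11), Tshz3 (3.07 ± 0.08) and the checkpoint receptor gene Lag3 (2.95 ± 0.12). For the 13 lists that camera did not call in this comparison, adjusted p ranged from 0.127 to 0.845. Among them were the germline genes, of which 0 of 19 passed, also adjusted over the list alone.

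In RH minus EV some lists also differed between the days. On day 12, 7 of 19 interferon response genes were higher, also adjusted over the list alone, with Oas2 at 0.60 ± 0.07 (adjusted p = 0.0631 with an estimated correlation). On day 16, 15 were lower and 1 higher (15 and 2 adjusted over the list alone; camera adjusted p = 7.37e-10), with Oasl1 at -1.49 ± 0.06. Of 20 late neutrophil genes 8 were lower and 2 higher on day 12 (10 and 2 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation), with Ltf at -1.06 ± 0.09. On day 16, 13 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 2.72e-07), with Ltf at 3.05 ± 0.09. So the day 12 calls of these 2 lists ended with an estimated correlation, and those of day 16 held. All 10 cholesterol synthesis genes were higher on day 12, also adjusted over the list alone (median 0.66, camera adjusted p = 3.94e-14), and on day 16 the list was not called, with 1 higher and 4 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.421). Insig1 was among the lower genes, at -0.42 ± 0.05. On day 12, 20 of 21 monocyte genes were lower, also adjusted over the list alone (camera adjusted p = 5.27e-22), and on day 16 the list was not called, with 8 higher and 6 lower (10 and 7 adjusted over the list alone; camera adjusted p = 0.596). The B lymphoid list was called lower on both days, and by more on day 16. On day 12, 5 of 12 genes were lower (7 adjusted over the list alone; median -0.34, camera adjusted p = 5.72e-05), with Dntt at -2.52 ± 0.08. On day 16, 10 were lower and 1 higher, also adjusted over the list alone (median -2.45, camera adjusted p = 1.02e-10), with Pax5 at -3.15 ± 0.07 and Cd22 at -3.84 ± 0.11, and the 1 higher was Dntt, at 1.33 ± 0.08, named after its value was seen. The RAS-MAPK output list was not called on day 12, with 3 higher and 5 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.675). On day 16, 13 of its genes were lower and 3 higher (15 and 3 adjusted over the list alone; camera adjusted p = 2.72e-07), with Egr1 at -2.56 ± 0.11. The inflammatory list was not called on day 12, with 6 higher and 5 lower (8 and 7 adjusted over the list alone; camera adjusted p = 0.587), and on day 16, 12 were higher and 1 lower (13 and 2 adjusted over the list alone; camera adjusted p = 0.000115). The interaction of arm and day was called for the interferon, late neutrophil, cholesterol, monocyte, B lymphoid and RAS-MAPK lists, with medians of -0.87, 1.555, -0.68, 0.85, -2.17 and -0.66 (camera adjusted p = 2.11e-13, 4.3e-09, 1.5e-09, 1.98e-09, 6.23e-08 and 2.37e-07), also with an estimated correlation. For the inflammatory list that call ended (median 0.42, adjusted p = 0.0502 with an estimated correlation).

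As the mean of both days 4396 genes differed between RH and EV, 2206 higher and 2190 lower, and 465 of them by at least 2-fold. On day 12 the count was 2986 (1354 higher, 1632 lower) and on day 16 it was 4771 (2622 higher, 2149 lower). A fit with only the arrays compared called 1359 on day 12 and 3022 on day 16, and the day 12 count was 1710 without the first EV array, 1815 without the first RH array and 1732 without the second. With the arrays centred, the splits were 909 higher and 2770 lower on day 12 and 1728 and 2774 for the mean of both days. Centring moved the median gene by -0.09 and -0.04 there, further from 0 than the -0.022 and -0.0174 before it.

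A set of 1512 genes was higher in RH than in both other arms and 1354 were lower, in the mean-of-both-days contrasts, and 435 genes passed in both with opposite signs. Independent lists of these sizes would share 346.4 and 345, but both contrasts use the RH arrays, which by itself raises the overlap. The RH arrays were then split so that 1 array of each day was set against WT and the other against EV. In the 4 possible splits 860 to 878 genes were higher and 808 to 826 lower, where independent lists would share 147.6 to 154.3 and 147.4 to 152.3. The arrays of a group were alike and may be repeats of a culture, so both parts carry the same departure of RH. The split thus does not make the lists independent, and nothing is concluded from the excess. With the arrays centred and not split, 1153 genes were higher and 1860 lower in RH than in both. Over all genes tested, 1512 of 22180 were higher in RH than in both and 1354 lower. Among the genes higher in RH than in both were 14 of 17 ribosome biogenesis, 11 of 19 mast cell, 9 of 12 megakaryocyte and 3 of 9 Hoxa genes. The share was larger than in the Hoxa list for 4 of 10 DNA methylation machinery, 4 of 10 cholesterol synthesis, 5 of 14 T and NK cell and 8 of 23 inflammatory genes. Among those lower than in both were 14 of 21 monocyte, 13 of 19 interferon response and 11 of 12 B lymphoid genes. These counts rest on means of both days. The interferon list was not called lower in RH on day 12, nor the monocyte list against EV on day 16.

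The third comparison set wild-type DNMT3A with NRAS G12D against NRAS G12D alone. Neutrophil genes were higher in WT as the mean of both days, with Ltf at 4.08 ± 0.06, Ly6g, the neutrophil surface marker, at 3.92 ± 0.06 and S100a8 at 3.46 ± 0.08. This difference was much larger on day 16, when the level in EV had fallen. The mean of the late neutrophil list was 8.88 in EV and 9.57 in WT on day 12, and 6.56 and 10.02 on day 16. Its interaction of arm and day had a median of 3.105. Hoxa9 was lower by -1.17 ± 0.11 and Mn1 by -1.24 ± 0.12. The largest decreases were in Gzmc (-4.86 ± 0.19), Mcpt2 (-4.34 ± 0.12), Ppbp (-4.29 ± 0.07), Dkkl1 (-4.15 ± 0.14) and Kitl, which encodes the Kit ligand, stem cell factor (-4.06 ± 0.12).

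In WT minus EV, 18 of 20 late neutrophil genes were higher and 2 lower (median 2.50, camera adjusted p = 5.54e-17). Of 12 primary granule genes 10 were higher (median 1.03, camera adjusted p = 8.98e-11), with Elane at 2.32 ± 0.05 and Mpo, the peroxidase gene, at 1.56 ± 0.05. Of 21 monocyte genes 13 were higher and 1 lower (camera adjusted p = 3.38e-07), with Mrc1 at 2.08 ± 0.05. Of 12 B lymphoid genes 10 were higher and 1 lower (median 0.55, camera adjusted p = 4.53e-06), with Igll1 at 1.44 ± 0.05. Of 19 interferon response genes 11 were higher and 1 lower (camera adjusted p = 9.34e-06), with Rsad2 at 1.60 ± 0.05. Of 10 cholesterol synthesis genes 7 were higher (camera adjusted p = 0.000356). Adjusted over the list alone, 11 primary granule, 11 B lymphoid and 8 cholesterol genes were higher and the other counts were the same.

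Lower in WT than in EV were 13 of 19 mast cell genes, with 4 higher (camera adjusted p = 5.27e-05), and 9 of 12 megakaryocyte genes, with 2 higher (camera adjusted p = 3.37e-05). So were 15 of 20 RAS-MAPK output genes, with 2 higher (camera adjusted p = 9.94e-09), and 10 of 14 dendritic cell and MHC class II genes, with 0 higher (camera adjusted p = 2.82e-09). Adjusted over the list alone, the RAS-MAPK count was 16 lower and 2 higher, the dendritic cell count 11 lower and 1 higher, and the others were the same. The antigen-presentation genes H2-Ab1 and Ciita differed by -1.96 ± 0.05 and -1.40 ± 0.07, and Spry1 and Egr2 by -1.79 ± 0.06 and -1.82 ± 0.09. Of 9 Hoxa genes 5 were lower and 1 higher, also adjusted over the list alone (adjusted p = 0.204 with an estimated correlation). Of 22 stem cell and leukaemia transcription factors 11 were lower and 5 higher (11 and 6 adjusted over the list alone; adjusted p = 0.0851 with an estimated correlation). Of 12 erythroid genes 4 were lower, also adjusted over the list alone (adjusted p = 0.0851 with an estimated correlation). These 3 calls ended. Mecom was lower by -2.15 ± 0.04 and the homeobox gene Nkx2-3 higher by 2.71 ± 0.11.

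Several of these differences in WT minus EV, too, were called on a single day. The primary granule list was not called on day 12, when 0 genes were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.444). On day 16 all 12 were higher, also adjusted over the list alone (camera adjusted p = 2.1e-13), with Elane at 4.56 ± 0.08 and Mpo at 3.06 ± 0.07. The dendritic cell and MHC class II list was not called on day 12, with 2 higher and 2 lower (camera adjusted p = 0.655), and on day 16, 10 were lower and 0 higher (camera adjusted p = 1.85e-09). These counts were the same adjusted over the list alone. All 10 cholesterol synthesis genes were higher on day 12, also adjusted over the list alone (camera adjusted p = 4.04e-13), and on day 16 the list was not called, with 2 higher and 4 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.304). The megakaryocyte list was called lower on day 12 (camera adjusted p = 1.68e-11) and not on day 16 (camera adjusted p = 0.0833), and the B lymphoid list was called higher on day 12 (camera adjusted p = 9.78e-11) and not on day 16 (camera adjusted p = 0.0833). For the mast cell list these values were 6.96e-13 on day 12, lower in WT, and 0.0522 on day 16. The interaction of arm and day was called for the first 5 of these lists, with medians of 2.27, -1.37, -0.72, 1.13 and -0.40 (camera adjusted p = 3.81e-16, 5.07e-09, 5.07e-09, 9.96e-06 and 0.00368), also with an estimated correlation. For the mast cell list that call ended (median 0.22, adjusted p = 0.0726 with an estimated correlation). The ribosome biogenesis list, not called as the mean of both days, was called lower in WT on day 12 (4 of 17 lower, 12 adjusted over the list alone; camera adjusted p = 8.68e-07). On day 16, 7 were higher (7 and 1 lower adjusted over the list alone), and that call ended (adjusted p = 0.0762 with an estimated correlation).

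As the mean of both days 5189 genes differed between WT and EV (2584 higher, 2605 lower), 676 of them by at least 2-fold. The count was 2342 on day 12 (1149 higher, 1193 lower) and 5841 on day 16 (2849 higher, 2992 lower). On day 12 it was 3535 with the trend and robust settings, 983 with only the arrays compared, and 1334 to 1443 without any 1 of the 4 EV and WT arrays of that day. On day 16 it was 3478 with only the arrays compared.

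**Figure D3:**
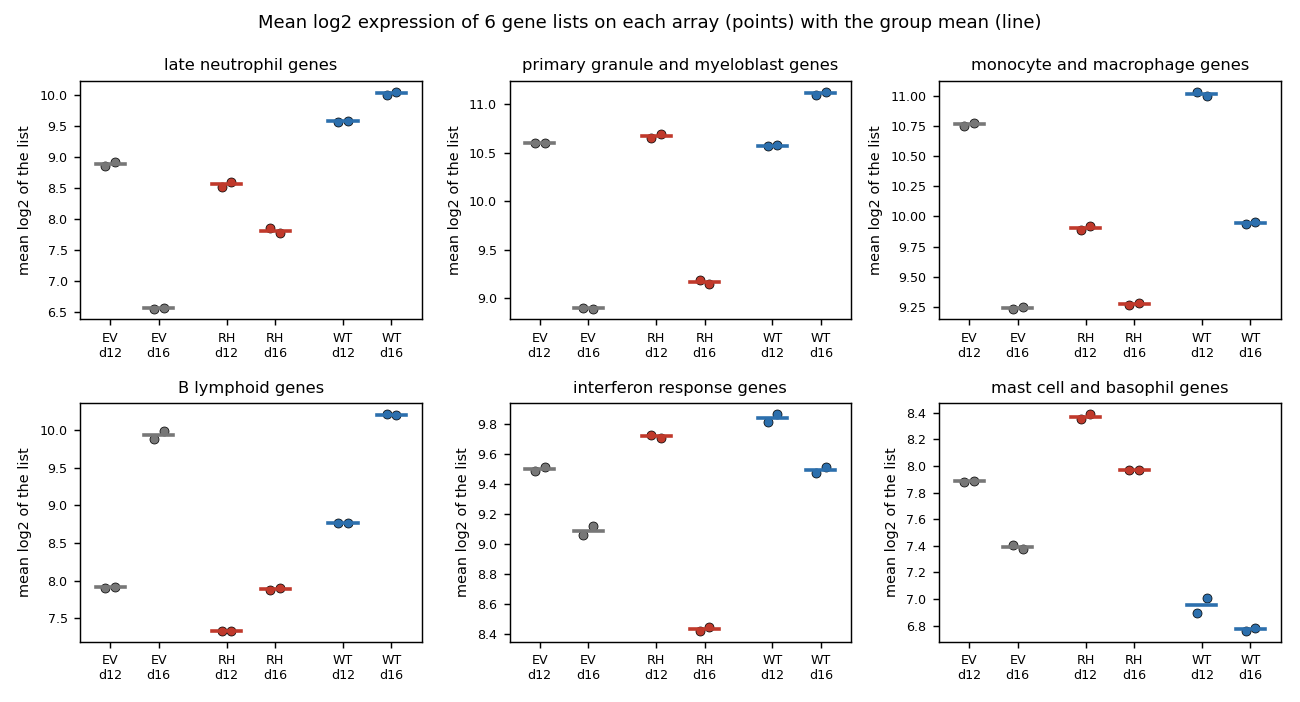
Mean log2 expression of the genes of 6 lists (vertical axes) on each of the 12 arrays, by arm and day (d12, d16; horizontal axes); points are arrays, lines are means of the 2 arrays, and the vertical axes do not start at 0. The late neutrophil mean fell from 8.88 to 6.56 in EV and was 9.57 and 10.02 in WT, where the call for the change between days ended with an estimated correlation, and the B lymphoid mean on day 16 was 9.93 in EV, 7.88 in RH and 10.20 in WT.

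Between day 12 and day 16 the EV arm lost neutrophil, monocyte and megakaryocyte transcripts and gained B lymphoid transcripts. Ltf fell by 5.03 ± 0.09 on the log2 scale and S100a8 by 4.31 ± 0.11, and Elane by 4.09 ± 0.08. Cr2 and Ms4a1, surface genes of mature B cells, rose by 5.49 ± 0.12 and 4.58 ± 0.17, Pax5 by 3.21 ± 0.07 and Igll1 by 3.13 ± 0.07. Lgr5 and Lef1, of the WNT pathway, rose by 5.13 ± 0.16 and 4.11 ± 0.07, and the progenitor marker Cd34 fell by 1.57 ± 0.06.

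In EV 18 of 20 late neutrophil genes fell and 2 rose (camera adjusted p = 3.86e-14), and 10 of 12 primary granule genes fell and 1 rose (camera adjusted p = 2.12e-09). Of 21 monocyte genes 18 fell (camera adjusted p = 1.06e-15), all 12 megakaryocyte genes fell (camera adjusted p = 2.29e-10), and 6 of 8 eosinophil genes fell (camera adjusted p = 0.000155). Of 12 B lymphoid genes 10 rose and 1 fell (median 2.39, camera adjusted p = 2.45e-10), and of 10 cholesterol synthesis genes 9 rose (median 0.87, camera adjusted p = 1.32e-09), with Cyp51 at 1.27 ± 0.06. Of 20 RAS-MAPK output genes 13 rose and 4 fell (camera adjusted p = 0.000553), with Egr2 at 2.51 ± 0.13 but Fos at -1.96 ± 0.06. Of 22 stem cell and leukaemia transcription factors 10 rose and 2 fell, with Gfi1b at 1.36 ± 0.07, and of 24 cell cycle genes 10 rose (camera adjusted p = 0.00436 and 0.000155). Of 19 interferon response genes 11 fell and 1 rose, and of 23 inflammatory genes 13 fell and 1 rose (camera adjusted p = 2.03e-05 and 8.69e-06), with the inflammatory gene Ccl2 at -2.31 ± 0.07. Adjusted over the list alone, 19 monocyte genes fell and 1 rose, 7 eosinophil genes fell, 10 cholesterol genes rose, and 14 RAS-MAPK genes rose and 5 fell. On the same basis 12 stem cell and leukaemia factors and 13 cell cycle genes rose, 12 interferon genes fell, and the other counts were the same. Of 19 mast cell genes 10 fell and 3 rose, of 15 p53 genes 8 and 1, and of 15 stress response genes 7 and 0 (10 and 3, 9 and 1, 8 and 0 adjusted over the list alone). These 3 calls ended, at an adjusted p = 0.0633, 0.0754 and 0.0616 with an estimated correlation.

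In the RH arm interferon response genes and primary granule genes fell. The granule genes Ms4a3, Ctsg and Elane fell by 4.09 ± 0.08, 4.05 ± 0.06 and 3.99 ± 0.08, while Dntt, the terminal transferase of lymphoid progenitors, rose by 2.89 ± 0.08. Of 19 interferon response genes 18 fell and 0 rose (19 and 0 adjusted over the list alone; median -1.17, camera adjusted p = 2.6e-28), with Oasl2 at -1.82 ± 0.07, Oasl1 at -1.68 ± 0.06 and Ifit1 at -1.65 ± 0.06. Hoxa9 rose by 0.61 ± 0.16, Meis1 by 0.52 ± 0.07 and Hoxa7 by 0.51 ± 0.06. Of 21 monocyte genes 16 fell (18 fell and 1 rose adjusted over the list alone), and of 20 late neutrophil genes 13 fell and 2 rose (16 and 2 adjusted over the list alone), at a camera adjusted p = 1.02e-14 and 1.31e-10. Of 12 primary granule genes 8 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 4.54e-07), and of 12 megakaryocyte genes 10 fell (12 adjusted over the list alone; camera adjusted p = 8.71e-12). Of 17 ribosome biogenesis genes 9 rose (13 adjusted over the list alone; camera adjusted p = 2.36e-06). Of 24 cell cycle genes 3 rose, also adjusted over the list alone, and of 23 inflammatory genes 8 fell and 2 rose (10 and 2 adjusted over the list alone), at a camera adjusted p = 0.00448 and 0.00407. The calls of the Hoxb, mast cell, eosinophil, B lymphoid and stress response lists ended, at an adjusted p = 0.0786, 0.0992, 0.0992, 0.0678 and 0.0992 with an estimated correlation.

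In the WT arm dendritic cell genes fell and B lymphoid and cell cycle genes rose. Siglech, a marker of plasmacytoid dendritic cells, fell by 4.56 ± 0.09, the integrin gene Itgax by 2.84 ± 0.07, and Spib, a factor of the same cells, by 3.85 ± 0.10. Of 14 dendritic cell and MHC class II genes 12 fell, also adjusted over the list alone (median -1.33, camera adjusted p = 5.71e-10). Of 12 B lymphoid genes 11 rose, also adjusted over the list alone (median 1.33, camera adjusted p = 3.55e-12), with Pax5 at 2.07 ± 0.07 and Ebf1 at 1.97 ± 0.06, and of 24 cell cycle genes 21 rose (22 adjusted over the list alone; median 0.30, camera adjusted p = 5.81e-10). Of 21 monocyte genes 19 fell (20 adjusted over the list alone; camera adjusted p = 9.16e-16), with C1qb at -2.88 ± 0.08. Of 12 primary granule genes 8 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0001), with Ms4a3 at 1.81 ± 0.08. Their change differed from that in RH and in EV, with interaction medians of -1.84 and 2.27 (camera adjusted p = 5.38e-09 and 3.81e-16). Of 17 ribosome biogenesis genes 11 rose (13 adjusted over the list alone), and of 20 RAS-MAPK output genes 13 rose and 3 fell (13 and 4 adjusted over the list alone), at a camera adjusted p = 2.76e-06 and 0.00117. Of 23 inflammatory genes 13 fell and 2 rose (14 and 2 adjusted over the list alone; camera adjusted p = 3.56e-05). The calls of the late neutrophil, megakaryocyte, T and NK cell, interferon response, stress response and cholesterol lists ended, at an adjusted p = 0.192, 0.136, 0.136, 0.0886, 0.192 and 0.136 with an estimated correlation.

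Between the days 6347 genes changed in EV (3122 rose, 3225 fell), 3341 in RH (1598 rose, 1743 fell) and 5783 in WT (2713 rose, 3070 fell). In RH the count was 1470 with only the arrays compared and 1919 to 1980 without any 1 of the 4 RH arrays, and in WT it was 3404 with only the arrays compared. With the arrays centred, 2221 genes rose and 4438 fell in EV, and 2006 rose and 3669 fell in WT. Centring moved the median gene by -0.095 in EV and -0.064 in WT, further from 0 than the -0.0031 and -0.0049 before it.

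Over the 3 mean-of-both-days contrasts camera called 14, 14 and 13 of the 27 lists at the preset correlation, in the order RH minus WT, RH minus EV and WT minus EV, and 11, 9 and 10 of these calls held with an estimated correlation. Over the day contrasts it called 15 in EV, 13 in RH and 14 in WT, of which 12, 8 and 8 held. The cell cycle call in RH minus EV also ended with the arrays centred or quantile normalized. Fry, whose p concerns movement of a list on balance and not relative to other genes, called 24, 18 and 21 lists in the first 3 and 24, 24 and 22 in the last.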

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

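The counts of splits were planned before the data were examined, and the tests on interferon response genes, on B lymphoid genes and on the number of differing genes were chosen only after the result was seen.

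The difference between arms differed between day 12 and day 16, by the interaction test in limma, for 3080 genes in RH minus WT, 3947 in RH minus EV and 3787 in WT minus EV. Genes called on both days but in opposite directions numbered 340, 677 and 314. Of the other named genes, 73 of 119, 78 of 110 and 67 of 112 had a difference between arms that differed between days.

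For gene lists that camera called in an interaction, values are medians of the arm difference on day 16 minus that on day 12. In RH minus WT they were 0.432 for the Hoxa cluster, -0.295 for stem and progenitor surface genes, -1.844 for primary granule genes, -1.337 for late neutrophil genes and 0.315 for monocyte genes. They were 1.31 for dendritic cell and MHC class II genes, -0.404 for megakaryocyte genes, -1.158 for B lymphoid genes, 0.703 for T and NK cell genes and 0.239 for stromal genes. For cell cycle genes the value was -0.213, for RAS-MAPK output genes -0.529, for interferon response genes -0.916, for inflammatory genes 0.322 and for hypoxia genes -0.067. In RH minus EV the medians were 1.555 for late neutrophil, 0.85 for monocyte, 0.812 for eosinophil, 0.593 for megakaryocyte and -2.167 for B lymphoid genes. There they were also -0.663 for RAS-MAPK output, -0.867 for interferon response, 0.418 for inflammatory, 0.357 for ribosome biogenesis and -0.682 for cholesterol synthesis genes. In WT minus EV they were 0.497 for stem and progenitor surface, 2.272 for primary granule, 3.105 for late neutrophil, 0.573 for monocyte, -1.368 for dendritic cell and 0.221 for mast cell genes. The remaining medians there were 0.92 for eosinophil, 1.126 for megakaryocyte, -0.396 for B lymphoid, -0.544 for T and NK cell, 0.151 for cell cycle, 0.358 for ribosome biogenesis and -0.722 for cholesterol synthesis genes. With an estimated correlation 9 of 15, 7 of 10 and 9 of 13 of these calls held. Those that ended were the Hoxa, stem and progenitor surface, megakaryocyte, stromal, inflammatory and hypoxia lists in RH minus WT, the eosinophil, megakaryocyte and inflammatory lists in RH minus EV, and the stem and progenitor surface, mast cell, eosinophil and T and NK cell lists in WT minus EV.

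Among the genes always reported, the interaction of RH minus WT was 0.462 for Meis1, 1.183 for Mn1, 0.659 for Hoxa5, 0.413 for Hoxa7, -0.908 for Kit, -0.875 for Cd34 and 0.31 for Itgam. In RH minus EV it was -0.492 for Dnmt3a, 0.846 for Hoxa9, 0.488 for Hoxa7, 1.556 for Cd34, 1.71 for Itgam and 0.962 for Csf1r. In WT minus EV it was -0.64 for Dnmt3a, -0.839 for Mn1, -0.508 for Hoxa5, 1.072 for Kit, 2.431 for Cd34, 1.4 for Itgam and 1.079 for Csf1r. Outside the gene test, in probe sets with several symbols or none, 2197 of 17824 differed between RH and WT as the mean of both days (1351 higher, 846 lower), 967 between RH and EV (628 higher, 339 lower) and 1015 between WT and EV (512 higher, 503 lower).

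Interferon response genes fell further in RH than in EV between the days, by a median of -1.169 against -0.347. With each array centred on its median the difference stayed at -0.768. Centring moved the median gene by only 0.099 here, so offsets left between array medians are too small to be the cause. The test shows no more than that. A greater loss of monocyte-like cells in RH would have lowered the monocyte list further there, and its median difference was 0.85, in the other direction. Each group had 2 arrays and the labels name no second culture, so a change in a single RH culture cannot be told apart from an effect of R882H over time.

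B lymphoid genes were lower in RH than in EV on day 16. With centred arrays the median difference was -2.437. The median gene moved by only 0.009 in that contrast, so offsets left between array medians are too small to be the cause. Suppose that a B-lineage population was the only source of these genes and only its share differed between EV and WT on day 16. The genes would then shift the same way. Of the 12 genes, 7 were called higher in WT and 3 lower (8 and 3 with centred arrays). They ranged from Dntt at 1.623 to Cd22 at -2.179, with a typical SE of 0.085, which argues against that case. Whether other cells also expressed some of these genes, such as Dntt, was not tested, so a changed share alone is not excluded. The SD of these differences was 0.981, under the bound of 1 that was first set for excluding a share alone, so that bound was not met. This test compared EV with WT and does not bear on the lower level in RH. For RH, a smaller share of B-lineage cells was not tested. In any arm, a change in the kind or stage of B-lineage cells, or in expression within cells, was not tested. These stay open, since bulk arrays do not separate them.

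In RH minus WT 6977 genes differed, 31.46% of those tested. With each array centred on its median, 7706 did. Centring moved the median gene by -0.072, further from 0 than the -0.0302 before it. A shift this small could hardly have lowered the count, so the test does not decide on scaling of whole arrays. The split between higher and lower does depend on centring, at 2640 and 5066 against 3483 and 3494. The correlation between arrays of an arm with the same number on both days was 0.01865, too low to show that the numbers mark lasting cultures. Each arm is a single construct, and a difference between infected cell pools could not be told apart from an effect of the construct.

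Splits of 8 arrays into 4 and 4 tested whether other groupings of single arrays call as many genes. Day was a term in 34 of the 35 splits, and the split by day was fitted without it, since the model cannot hold both. For RH against WT the real split gave 4382 genes and the highest of the others, the one by day, 408. So 1 of 35 gave as many, a share under 0.05. That share does not exclude chance by itself, since a split that breaks up a group of like arrays raises the spread and calls fewer genes. For RH against EV the real split gave 1251 and the split by day 1596, and for WT against EV 1735 and 2718, so 2 of 35 gave as many, which by the planned count does not exclude chance. That split measures the change between the days and does not arise by chance, and without it, a choice made after the values were seen, 1 of 34 gave as many in each, with 544 and 95 as the highest others. Arrays of a group were alike and are not known to be separate cultures, and 3 of the 35 splits keep the groups whole, too few for a share under 0.05, so these counts say nothing on chance differences between cultures.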

How the results depend on the processing

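The alternatives were all planned, and no tests in this part were chosen after the result was seen. The 16 gene counts stayed within 1.5 times of the reported values under quantile normalization, centring, both level filters, every probe set, the mean of probe sets, array weights and both blocks, and a result called in neither setting counts as unchanged. With only the arrays compared, which leaves fewer arrays to estimate the spread, counts fell to 1359 for RH minus EV on day 12 and 3022 on day 16, 983 and 3478 for WT minus EV, and 1470 and 3404 for the day contrast in RH and WT. Trend and robust settings gave 3535 for WT minus EV on day 12, and the cause was not tested. Leaving out each array in turn gave 1710 to 2008 for RH minus EV on day 12, 1334 to 1443 for WT minus EV on day 12 and 1919 to 1980 for the day contrast in RH. A lone array left in a group was assumed to vary like the other groups.

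Camera with an estimated correlation called 8 lists in RH minus WT on day 12, 4 in RH minus EV on day 12, 5 in WT minus EV on day 16, 9 in RH minus EV over both days, 8 each in the day contrasts of RH and WT, and 9 in the interaction of RH minus WT. In WT minus EV on day 16, 13 lists were called with centred arrays and 13 with every probe set, against 8, and 9 in the day contrast of WT with genes at or above the median level. The cause of these 3 was not tested. Fry, which does not compare a list with other genes, called 24 and 23 lists in RH minus WT on days 12 and 16, 22 and 20 in RH minus EV, and 22 in WT minus EV on day 16. It called 24 in RH minus WT and 21 in WT minus EV over both days, 24, 24 and 22 in the day contrasts of EV, RH and WT, and 23, 24 and 22 in the interactions of RH minus WT, RH minus EV and WT minus EV.

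Reversed with the mean of probe sets were Car9 in the day contrast of EV (-0.03 against 0.421) and Slc2a1 in RH minus EV on day 12 (-0.044 against 0.24) and in WT minus EV on day 16 (0.042 against -0.219), and the cause was not tested. The direction of fry was opposite to that of camera for hypoxia genes in WT minus EV (median 0.005), RAS-MAPK output genes in RH minus WT on day 16 (0.033) and stem cell and leukaemia factors in RH minus EV on day 16 (0.004). Centring also moved the split of the interactions, to 2103 higher and 1103 lower for RH minus WT, against 1698 and 1382, and 3088 and 1286 for RH minus EV, against 2217 and 1730. It moved the median gene by 0.068 and 0.099 there, further from 0 than the 0.0166 and 0.0204 before it. Replicate numbers do not pair the arrays, since deviations of the same number correlated at -0.0531 to 0.0419 over 15 pairs of groups. With the number as a block 6712 genes differed in RH minus WT over both days, 3 list calls and 34 calls of named genes ended, and 0 directions turned. Calls of named genes that ended were more with only the arrays compared (161), every probe set (93) and centring (46), and fewer with the mean of probe sets (22), quantile normalization (17), trend and robust settings (10), array weights (3) and the random block (2). Over all leave-one-out fits 666 such calls ended, 7 began and 8611 results were unchanged, and for lists 33 ended, 29 began and 2206 were unchanged. Of list calls 62 ended with an estimated correlation, 27 with genes at or above the median level, 14 with those at or above the 25th percentile, 6 each with centring, quantile normalization, every probe set and only the arrays compared, and 4 with the mean of probe sets. Fry added 138 list calls, every probe set 19 and centring 13. Signal over background was not available, so what dim probe sets can show is unknown.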

Other observations

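The 5 gene families below, and the tests on them, were chosen only after the result was seen, and camera p-values were adjusted over 75 tests of 5 families in 15 contrasts.

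Genes of the stefin A and cystatin A family, which encode inhibitors of cysteine proteases, were higher in WT than in EV as the mean of both days for 8 of 13 members (median 2.49, camera adjusted p = 3.5e-07). Against EV, 9 were higher in RH (median 1.08, camera adjusted p = 6.73e-06), and by day they were 1 on day 12 (median -0.03, camera adjusted p = 0.354) and 8 on day 16 (median 1.75, camera adjusted p = 5.54e-06). Between the days 8 fell in EV (median -1.74, camera adjusted p = 0.000133), and in RH 0 passed and the median was -0.115 (camera adjusted p = 0.422). The interaction of RH minus EV with day was called for this family (median 1.53, camera adjusted p = 3.72e-05). All 8 Gimap genes, GTPases of lymphocytes, rose in EV (median 2.31, camera adjusted p = 2.89e-09), 7 rose in WT (median 0.87, camera adjusted p = 1.45e-06) and 4 in RH (median 0.58, camera adjusted p = 3.03e-05). That rise differed from EV in both other arms, with interaction medians of -1.38 for WT and -1.685 for RH (camera adjusted p = 5.22e-07 and 5.65e-09).

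Of 12 toll-like receptor genes, sensors of microbial molecules, 10 were lower in RH than in WT as the mean of both days (median -0.74, camera adjusted p = 3.5e-07). Against EV, 10 were lower in RH on day 12 (median -0.63, camera adjusted p = 1.21e-11), and on day 16, 2 were higher and 4 lower (median 0.003, camera adjusted p = 0.501). That difference between days was called (interaction median 0.86, camera adjusted p = 3.45e-06). Between the days 11 fell in EV, 10 in RH and 11 in WT (medians -1.095, -0.51 and -0.96). Of 9 genes of the Ifi200 family, which interferon induces, 7 fell in RH between the days (median -1.32, camera adjusted p = 1.5e-08), and in EV 3 rose and 4 fell (camera adjusted p = 0.304). The change was not shown to differ between these arms, with an interaction median of -0.445 (camera adjusted p = 0.0947). Of 10 Gbp genes, GTPases that interferon induces, 5 were higher in RH than in EV and 1 lower (median 0.32, camera adjusted p = 0.00167), and 6 fell in WT between the days (median -0.34, camera adjusted p = 0.00167). In RH minus WT 4 were higher and 1 lower, and the family was not called (camera adjusted p = 0.0989). The calls named here held with an estimated correlation, at an adjusted p of 0.0279 or below.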
